A study of Mus musculus with 19 samples.

How the data were processed

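Ovaries of female C57BL/6 mice, an inbred laboratory strain, were frozen on dry ice and RNA was isolated with a column kit for DNA and RNA, per the labels. Sequencing libraries were made with a kit that keeps the strand of the RNA, per the labels' protocols. The aligner, the counting method and whether the counting used strand are not given in the sources used here. Counts of paralogs and multigene families such as Oas1, Khdc1, Obox, Mup and Pcdhb, and of overlapping or antisense genes, are therefore uncertain. The genome build was mm10, per the submitters' processing notes, and genes were RefSeq models, per the file headers. Each of the 19 libraries was placed in its age group by its age label and matched to its columns of values by its title. The labels give no batch and no replicate number shared between ages, and number the libraries in order of age, so any effect of handling order would follow age. They do not give the time of day or the stage of the oestrous cycle at collection.

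The authors deposited raw values per gene as estimated counts that need not be whole, per the file headers and the values, in a table of 36172 genes. Between 17.4% and 21.4% of the nonzero values of a library were whole numbers within 1e-08. Library totals ran from 10851519 to 14302207 estimated counts. The estimated counts were rounded to whole numbers before any count test. The authors also deposited log2 values, normalized across libraries by a method not given in the sources used here and set relative to the median of the 3 month libraries. A second table of these log2 values held 13869 genes, and all 13869 met the filter in its header, a raw value of at least 20.0 in every library of at least 1 of the 4 ages. Each table has 1 further column of per-library values that matches no sample, and it was not used here. Of the 36172 rows 32943 were matched to the reference annotation by NCBI gene ID, and 454 rows share a symbol with another. Gene length and GC content were known for 99.3% of the genes tested.

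Counts were tested with edgeR's quasi-likelihood test (robust, TMM scaling, a mean per age over all 19 libraries) after edgeR's filter on low counts (minimum count 10, minimum total 15), which left 15518 genes. The linear trend was fitted on age in months and is given as the change over 9 months. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Values per gene are CPM, counts scaled to library size with TMM factors, as mean ± SD, and log2 changes carry a standard error (SE). Of 37 gene lists with 732 entries, 15 entries had no gene in the table, and 36 lists had at least 5 members tested. The list of mitochondrially encoded genes had fewer and was not tested. Lists were tested with limma's camera on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the lists. The replicate check was a chi-square of each pair of libraries of one age.

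The samples, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule names 8 rising and 8 falling genes between 3 and 12 months with the largest change among those past the threshold, with a mean of at least 1 CPM and no overlap between the ages. For the trend it names the 5 rising and 5 falling genes with the smallest p whose group means follow age, and for the other comparisons the 3 rising and 3 falling with the smallest p. From each list it takes up to 4 members with the smallest p at 12 months or along the trend, and, where none passed, the 2 with the highest mean. Cdkn1a, Cdkn2a, Il6, Amh, Gdf9, Zp3, Col1a1, Adgre1 (Emr1 in the tables), Dnmt1, Dnmt3a, Tet1 and Ezh2 are always named. Predicted genes and pseudogenes are counted and not named under the first parts of the rule. The rule gives 166 genes, of which the text prints a part, and some are not reported here.

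Alternatives fixed in advance were size factors of the DESeq kind, DESeq2, limma-voom with sample weights, limma-trend on the authors' log2 values, no filter, a filter of CPM 1 in 4 libraries, 2 surrogate variables, the corpus luteum list as a covariate, an adjusted p under 0.01, a doubling or halving, only the ages compared, and each library left out in turn. Leaving out the libraries with lymph node or liver transcripts, a length and GC correction and the oviduct list as a covariate were added after seeing the data, as were the lists of liver, lymph node and clock genes. The steps were tested on simulated counts with known changes. For 12 against 3 months, with 15386 genes, the test recovered 33 of 67 genes changed 1.5-fold, 57 of 67 changed 2-fold and 62 of 66 changed 4-fold, with 8 false calls. For the trend, with 15373 genes, it recovered 39 of 67, 56 of 67 and 63 of 66 at the same folds, with 7 false calls. Camera called a simulated list of 20 genes shifted by 0.5 (log2) and 0 unchanged lists. The simulated genes varied independently of each other, so this cannot test camera on lists whose members move together. Each simulated gene had the same spread at every age, while real libraries varied more at 9 and 12 months than at 3 and 6. The simulated rates of recovery and false calls may therefore not hold for the real data. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.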

Results

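Whole-ovary RNA from female mice of the inbred C57BL/6 strain was sequenced at 3, 6, 9 and 12 months of age, a span over which the follicle reserve of the mouse ovary declines. There were 5 libraries at 3 months, 5 at 6 months, 5 at 9 months and 4 at 12 months, with totals of 10851519 to 14302207 estimated counts per library. Of the 36172 genes in the table, 15518 passed the low-count filter and were tested. Libraries of the same age differed by more than counting noise, with a chi-square per degree of freedom between 5.11 and 38.86 for every pair, so no library was counted as a repeat of another. The biological coefficient of variation was 13.5% at 3 months, 11.4% at 6 months, 22.6% at 9 months and 23.7% at 12 months. The labels do not say whether each library came from a separate mouse, so p-values measure only the spread between these libraries, which may be technical.

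**Figure D1:**
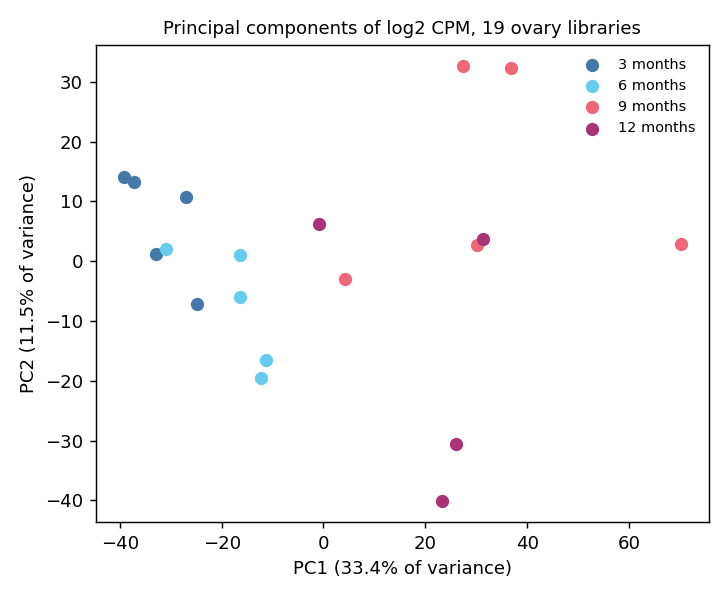
Principal components of log2 CPM (counts scaled to library size) in the 19 ovary libraries (points), coloured by age, with PC1 (33.4% of variance) on the x axis and PC2 (11.5%) on the y axis. The 3 and 6 month libraries lie between -39.26 and -11.28 on PC1, and the 9 and 12 month libraries between -0.94 and 70.16.

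Between 3 and 12 months, 29 of 30 oocyte genes and 21 of 24 proliferation genes fell, while 15 of 27 interferon response, 9 of 19 macrophage and 6 of 14 endothelial genes rose. The shifts of these lists by camera were lost with an estimated correlation (adjusted p = 0.329 to 0.423). By limma's fry test each of these lists moved (fry adjusted p = 0.00126 to 0.0292). That test asks whether the members changed, not whether they changed more than other genes. Gdf9, an oocyte growth factor, went from 63.3 ± 11.2 CPM (SD, n = 5) to 18.04 ± 7.62 CPM (SD, n = 4). By edgeR's quasi-likelihood test 3475 of the 15518 genes changed, 1693 upward and 1782 downward. Of these, 463 rose by at least a doubling and 299 fell by at least a halving. Of the genes tested, 2560 (16.5%) had every 12 month library on one side of every 3 month library, where chance gives 1.6%, and 2136 of these were called. Without 12 month replicate 3 the count of changed genes was 2124. With a correction for gene length and GC content, chosen after seeing the data, it was 2759, and 2271 of the 3475 (65.4%) stayed called.

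**Figure D2:**
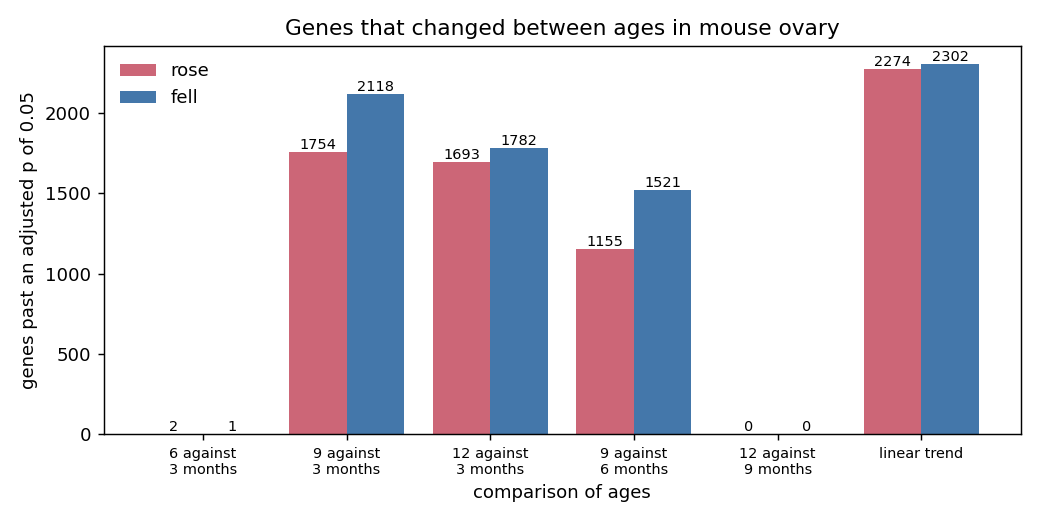
Number of genes past an adjusted p of 0.05 (edgeR quasi-likelihood test) that rose or fell (bars, from 0) in each comparison of ages and along the linear trend. The comparison of 6 with 3 months has 2 and 1 genes and that of 12 with 9 months has 0, against 1754 and 2118 for 9 with 3 months.

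In the oocyte list, 29 of 30 measured members fell at 12 months and 30 fell when adjusted over the list alone, with a median log2 change of -1.76 (camera adjusted p = 1.5e-16; adjusted p = 0.418 with an estimated correlation). Gdf9 fell by 1.81 ± 0.37 (log2, SE) and Zp3, a zona pellucida glycoprotein, fell by 1.75 ± 0.43. Oog1 fell by 1.55 ± 0.23 and H1foo, the oocyte linker histone, fell by 1.74 ± 0.32. Of 9 measured genes of primordial follicle oocytes 7 fell (8 adjusted over the list alone), with a median of -1.56 (camera adjusted p = 2.33e-05; adjusted p = 0.329 with an estimated correlation). The germ cell RNA-binding protein gene Dazl (-1.57 ± 0.33) and the oocyte transcription factor gene Nobox (-1.79 ± 0.50) were among them. In the mm10 build Gdf9 lies on chromosome 11 from 53430774 to 53437904 and Zp3 on chromosome 5 from 135980105 to 135988624.

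Genes of the cells around the oocyte changed in part. Of 20 granulosa cell genes of growing follicles 3 fell, 3 also adjusted over the list alone, with a median of -0.11 (camera adjusted p = 0.12). They were Amh, the anti-Müllerian hormone (-1.21 ± 0.32; log2, SE), the oestrogen receptor gene Esr2 (-0.86 ± 0.21) and Slc18a2, a monoamine transporter (-1.68 ± 0.29). The call on Amh was lost without 12 month replicate 3 (log2 change -1.11). Of 15 theca and interstitial genes 5 fell and 2 rose (6 and 2 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 0.00632; adjusted p = 0.423 with an estimated correlation). Cyp17a1, the enzyme of androgen synthesis, went from 541 ± 137 CPM (SD, n = 5) to 80.0 ± 28.0 CPM (SD, n = 4), and the peptide hormone gene Insl3 (-1.49 ± 0.32) and Enpep (-0.82 ± 0.21) also fell. Of 15 steroidogenesis genes 2 fell, Cyp17a1 among them, 2 also adjusted over the list alone (median -0.15; camera adjusted p = 0.131). Of 14 corpus luteum genes 2 rose, 2 also adjusted over the list alone, with a median of -0.04, a mean of 0.14 and an upward camera direction (camera adjusted p = 0.878). One of them, the betaine methyltransferase gene Bhmt, was at 84.2 CPM in 12 month replicate 4 and at 0.84 to 1.78 CPM in the other 12 month libraries, and its log2 change without replicate 4 was -0.456. In the 9 month libraries Bhmt was at 5.52 to 64.3 CPM. The call on Bhmt was also lost without 3 month replicate 1, 2, 3 or 5 (log2 change 3.59 to 3.80). The other corpus luteum gene that rose, Lhcgr, lost its call without 3 month replicate 1, 3, 4 or 5 or 12 month replicate 1, 3 or 4 (log2 change 0.98 to 1.51). Of 16 ovulation response genes 2 rose and 1 fell, the signalling regulator Rgs2 (-0.73 ± 0.18), with 2 and 1 adjusted over the list alone (median 0.21; camera adjusted p = 0.204). The calls on the 2 that rose, Areg and Edn2, were both lost without 12 month replicate 1 or 3 (log2 change 0.98 to 1.09).

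Most genes of cell division fell, as did part of those of DNA repair, DNA methylation and histone modification. Whole-ovary RNA cannot tell a lower level within cells from fewer cells that hold the transcript, for these lists or the others. Of 24 proliferation genes 21 fell (24 adjusted over the list alone), with a median of -0.70 (camera adjusted p = 2.8e-11; adjusted p = 0.423 with an estimated correlation). The centromere protein gene Cenpf fell by 0.87 ± 0.16 (log2, SE) and the mitotic cyclin Ccnb1 by 1.02 ± 0.20. Of 25 DNA repair genes 13 fell (15 adjusted over the list alone; camera adjusted p = 1.08e-05; adjusted p = 0.423 with an estimated correlation). Brca1 (-0.99 ± 0.21), the checkpoint kinase Atr (-0.48 ± 0.09) and the mismatch repair gene Msh6 (-0.54 ± 0.08) were among them. Of 15 genes of the DNA methylation machinery 6 fell (8 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00632; adjusted p = 0.221 with an estimated correlation). The maintenance methyltransferase gene Dnmt1 fell by 0.71 ± 0.13 and the de novo enzyme gene Dnmt3a fell by 0.25 ± 0.06. The methylcytosine dioxygenase genes Tet1 and Tet3 fell by 0.49 ± 0.09 and by 0.32 ± 0.07. Of 35 genes for histone methyltransferases, demethylases and deacetylases 12 fell, 12 also adjusted over the list alone, with a median of -0.09 (camera adjusted p = 0.0117; adjusted p = 0.423 with an estimated correlation). Ezh2, the Polycomb methyltransferase, fell by 0.78 ± 0.14. With a correction for gene length and GC content, chosen after seeing the data, 5 members of this list fell and 1 rose. Dnmt1 lies on chromosome 9 from 20907206 to 20959888 and Ezh2 on chromosome 6 from 47530274 to 47595270.

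Part of the immune and interferon genes rose. Of 27 interferon response genes 15 rose (18 adjusted over the list alone), with a median of 0.75 (camera adjusted p = 3.61e-06; adjusted p = 0.423 with an estimated correlation). The antiviral genes Oas1a (1.68 ± 0.23; log2, SE) and Bst2 (0.42 ± 0.08) and the ISG15 protease gene Usp18 (0.75 ± 0.18) were among them. Of 19 macrophage genes 9 rose (13 adjusted over the list alone; camera adjusted p = 4.88e-05; adjusted p = 0.423 with an estimated correlation). Cd68 (0.94 ± 0.22) and the complement subunit gene C1qc (0.77 ± 0.18) rose, while Emr1, which encodes the macrophage marker F4/80, had a change of 0.31 ± 0.26 and did not pass the test. Of 23 T and NK cell genes 13 rose (15 adjusted over the list alone), with a median of 1.91 (camera adjusted p = 0.00025; adjusted p = 0.473 with an estimated correlation). Of 11 B and plasma cell genes 7 rose (9 adjusted over the list alone), with a median of 3.34 (camera adjusted p = 0.0171; adjusted p = 0.473 with an estimated correlation). Igj, the joining chain of secreted immunoglobulins, went from 7.28 ± 3.18 CPM (SD, n = 5) to 137 ± 93.1 CPM (SD, n = 4). Of 9 mast cell and granulocyte genes 5 rose, 5 also adjusted over the list alone (camera adjusted p = 0.000349; adjusted p = 0.221 with an estimated correlation). The mast cell protease genes Tpsb2 (2.16 ± 0.33), Cpa3 (1.94 ± 0.31) and Cma1 (1.86 ± 0.30) were among them.

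Of 10 MHC class II presentation genes 5 rose (10 adjusted over the list alone), H2-DMb1 by 1.04 ± 0.27 (log2, SE; camera adjusted p = 0.000616; adjusted p = 0.423 with an estimated correlation). The mean log2 CPM of that list was 6.57 in 12 month replicate 2 and 4.95 to 5.16 in the other 12 month libraries. Of 25 cytokine and chemokine genes 8 rose (9 adjusted over the list alone; camera adjusted p = 0.000844; adjusted p = 0.423 with an estimated correlation). The chemokine genes Ccl8 and Cxcl16 rose by 2.79 ± 0.40 and by 0.84 ± 0.16. Of 17 giant cell and foam cell genes 5 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0218; adjusted p = 0.423 with an estimated correlation). Cd5l, a secreted macrophage protein, rose by 2.62 ± 0.51 and the integrin gene Itgax by 1.81 ± 0.34. Of 17 complement genes 7 rose, C3 among them (1.38 ± 0.33), and 3 fell, with 7 and 4 adjusted over the list alone (camera adjusted p = 0.163). The cytokine gene Il6 had at most 10.2 estimated counts in any library and was not tested.

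Lymphocyte transcripts were uneven between the old libraries. Cd79a, part of the B cell receptor, was at 50.3 CPM in 12 month replicate 2, at 0.52 to 3.93 CPM in the other 12 month libraries and at 23.7 and 32.4 CPM in 9 month replicates 1 and 2. In the same 3 libraries Glycam1, a gene of lymph node vessels, was at 34.0, 6.7 and 26.5 CPM. Cr2, a complement receptor gene of follicular lymphoid cells, was at 12.6, 6.15 and 10.7 CPM, against at most 0.84 CPM in the others, and was chosen after its values were seen. With the 3 libraries over 5 CPM of Cr2 left out, a setting chosen after seeing the data, 3878 genes changed between 3 and 12 months and 28 of 30 oocyte genes fell. In that setting 4 of 20 T and NK cell genes rose (median 0.50), as did 5 of 10 B and plasma cell genes (median 1.33). Of the interferon genes 9 of 27 rose there (median 0.40), and of the macrophage genes 7 of 19. Of the genes of antigen presentation by MHC class II 4 of 10 rose in that setting between 3 and 12 months and 5 along the linear trend.

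**Figure D3:**
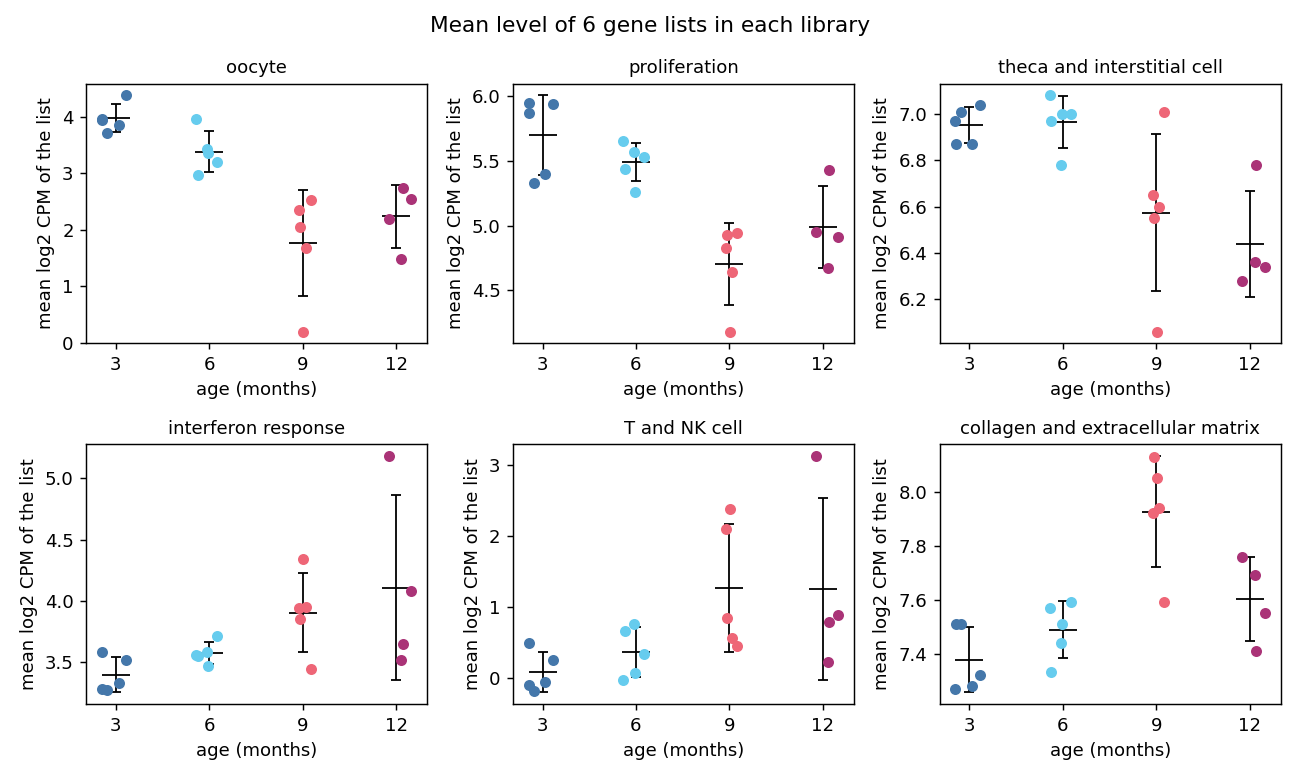
Mean log2 CPM (y axis) of 6 gene lists in each library (points) by age in months (x axis), with the group mean and SD (bar and whiskers). The oocyte list lies at 3.72 to 4.38 in the 3 month libraries and 1.48 to 2.75 in the 12 month libraries, and the T and NK cell list reaches 3.12 in 12 month replicate 2.

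Stromal, vascular and epithelial genes rose in part. Of 28 collagen and matrix genes 9 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 0.0068; adjusted p = 0.473 with an estimated correlation). Col1a1, a chain of the main fibrillar collagen, rose from 361 ± 50.0 CPM (SD, n = 5) to 585 ± 136 CPM (SD, n = 4), a call lost without 12 month replicate 3 (log2 change 0.54). Col6a2 rose by 0.58 ± 0.12 (log2, SE), and the matrix glycoprotein gene Thbs1 fell by 0.73 ± 0.12. Of 14 endothelial genes 6 rose (7 adjusted over the list alone; camera adjusted p = 0.000212; adjusted p = 0.329 with an estimated correlation). Plvap, a protein of fenestrated endothelium, rose by 1.19 ± 0.23 and the adhesion gene Pecam1 by 0.38 ± 0.09. Of 12 ovarian surface epithelium genes 5 rose (7 adjusted over the list alone), the keratin gene Krt7 by 1.15 ± 0.17 (camera adjusted p = 0.000844; adjusted p = 0.423 with an estimated correlation). Of 12 smooth muscle and pericyte genes 5 rose (8 adjusted over the list alone), the actin-binding protein gene Tagln among them (0.73 ± 0.19; camera adjusted p = 0.0124; adjusted p = 0.423 with an estimated correlation), a call lost without 12 month replicate 3 (log2 change 0.54), and 2 rose with the length and GC correction. The calls on Des, Smtn and Actg2 were lost without 12 month replicate 3 too (log2 change 1.01, 0.29 and 0.72). Of 18 oviduct genes 3 rose (2 adjusted over the list alone), the cilium gene Tekt4 by 0.81 ± 0.20 (camera adjusted p = 0.022; adjusted p = 0.622 with an estimated correlation). Ovgp1, the oviduct glycoprotein, was at 1624 to 6152 CPM over the libraries. It and 1700009P17Rik, the other oviduct genes that rose, lost the call without 12 month replicate 1 or 3 (log2 change 0.40 to 0.74). With the mean of the oviduct list as a covariate, chosen after seeing the data, 2463 genes changed, 25 oocyte genes fell and 1 smooth muscle gene rose.

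Genes tied to cellular senescence changed in part. Of 12 cell cycle inhibitors and related senescence genes 0 rose and 2 fell by edgeR's test, 2 also adjusted over the list alone, with a median of -0.05 and a mean of 0.01 (camera adjusted p = 0.556). Lmnb1, the nuclear lamin B1, fell by 0.60 ± 0.14 (log2, SE). Cdkn1a, which encodes p21, was at 33.3 ± 13.1 CPM at 3 months (SD, n = 5) and 34.5 ± 8.29 CPM at 12 months (SD, n = 4), a change of 0.05 ± 0.24. Cdkn2a, which encodes p16 and p19, was at 1.59 ± 0.874 and 3.16 ± 1.40 CPM, a change of 0.98 ± 0.47 with edgeR adjusted p = 0.137. Of 30 genes of the senescence associated secretory list 4 rose (3 adjusted over the list alone), Ccl8 among them (camera adjusted p = 0.083). In that list 7 rose and 1 fell along the linear trend (7 and 1 adjusted over the list alone; camera adjusted p = 0.0334; adjusted p = 0.388 with an estimated correlation), and 9 rose and 1 fell between 3 and 9 months (11 and 1 adjusted over the list alone; camera adjusted p = 0.0041; adjusted p = 0.235 with an estimated correlation). Cdkn1a lies on chromosome 17 from 29090979 to 29100722 and Cdkn2a on chromosome 4 from 89274473 to 89294619.

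In each of the further lists fixed in advance fewer members changed than did not. Of 15 adipocyte genes 2 fell, 2 also adjusted over the list alone, with a median of -0.70 (camera adjusted p = 0.0472; adjusted p = 0.622 with an estimated correlation). The leptin gene Lep was one of them (-1.85 ± 0.58; log2, SE), a call lost without 3 month replicate 3 or 4 or 12 month replicate 1 or 4 (log2 change -1.77 to -1.57). Of 26 antioxidant genes 4 rose, the glutathione peroxidase gene Gpx1 (0.84 ± 0.14) among them, and 2 fell, with 4 and 2 adjusted over the list alone (camera adjusted p = 0.159). Of 36 nuclear genes of mitochondrial complex I 4 rose and 1 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.0723). Of those that rose, Ndufb11, Ndufb7 and Ndufa11 lost the call without 12 month replicate 3 (log2 change 0.195, 0.235 and 0.319). Of 22 cholesterol synthesis genes 2 rose, 2 also adjusted over the list alone (camera adjusted p = 0.772). Of 19 matrix protease and inhibitor genes 2 rose and 1 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.338). Of 7 lymphatic endothelium genes 2 rose and 1 fell (2 and 2 adjusted over the list alone), with a median of -0.01 and an upward camera direction (camera adjusted p = 0.878). Of 17 heat shock and unfolded protein genes 3 rose, Sdf2l1 (0.89 ± 0.15) among them, and 3 fell, the chaperone gene Hsp90aa1 (-0.49 ± 0.11) among them, with 4 and 4 adjusted over the list alone (camera adjusted p = 0.652). Of 17 immediate early genes 1 rose (0 adjusted over the list alone; camera adjusted p = 0.131). Of 6 erythrocyte genes 0 passed the edgeR test, 0 also adjusted over the list alone (camera adjusted p = 0.163). In lists of clock genes made after seeing the data, 5 of 8 genes driven by the circadian activator Bmal1 rose and 5 of 6 of the opposite phase fell. By camera 13 lists shifted up and 8 down of 36, and with an estimated correlation 0 did. By limma's fry test 17 lists moved.

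Among called genes with a mean of at least 1 CPM and no overlap between the ages, those with the widest change between 3 and 12 months came from different groups. Comp, a cartilage matrix protein, was at 41.7 and 37.9 CPM in 12 month replicates 1 and 3, at 1.07 and 2.19 CPM in the other 12 month libraries and at 0.765 ± 0.208 CPM at 3 months (SD, n = 5). Igj and the B cell transcription factor genes Pou2af1 and Spib rose by 4.23 ± 0.72, 4.90 ± 1.26 and 3.46 ± 1.07 (log2, SE), and the serine protease gene Prss29 by 4.83 ± 1.18. Prss29 was at 7.98, 1.07, 5.12 and 0.3 CPM in 12 month replicates 1 to 4. It was also at 0.3 CPM in 3 month replicate 1, so for Prss29 the gap between the ages was smaller than the rounding. Zfp831 rose from 0.133 ± 0.150 CPM to 2.31 ± 2.35 CPM. Glycam1 was at 0.16, 34.0, 0.15 and 0.3 CPM in 12 month replicates 1 to 4, at 0.14 CPM in 3 month replicate 3 and at 0.00 CPM in the other 3 month libraries. The call on Pou2af1 was lost without 12 month replicate 2 (log2 change 2.86), that on Glycam1 without 3 month replicate 3 or 12 month replicate 2 (log2 change 9.84 and 2.45) and that on Spib without 12 month replicate 2 (log2 change 1.41) and without 3 month replicate 1, 4 or 5 (log2 change 3.26 to 3.44). Downward, Scd1, a fatty acid desaturase, went from 1832 ± 1117 to 256 ± 102 CPM (SD, n = 5 and 4) and Pnpla3, a lipid droplet protein, from 19.8 ± 9.43 to 3.25 ± 1.90 CPM. Adipocyte transcripts were high in libraries where both were high: in 3 month replicates 3 and 4 the adipocyte list had a mean log2 CPM of 6.97 and 6.68, against 5.32 to 6.15 in the other 3 month libraries, with Scd1 at 3490 and 2413 CPM and Pnpla3 at 31.1 and 27.9 CPM. In 9 month replicate 1, with a list mean of 7.87, Scd1 was at 3217 CPM and Pnpla3 at 32.1 CPM. Cyp17a1 fell by 2.76 ± 0.73, the oocyte genes Khdc1c and Obox5 by 2.43 ± 0.57 and by 2.30 ± 0.42, and D6Ertd474e by 2.20 ± 0.54. The plasma protein genes Orm1 and Mbl2 fell by 2.23 ± 0.77 and by 2.20 ± 0.68. The call on Mbl2 was lost without 3 month replicate 3 or 12 month replicate 1 or 3 (log2 change -2.08 to -1.95), and that on Orm1 without 3 month replicate 1, 3, 4 or 5, 6 month replicate 2, 4 or 5, 9 month replicate 3 or any 12 month replicate (log2 change -2.66 to -1.80).

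**Figure D4:**
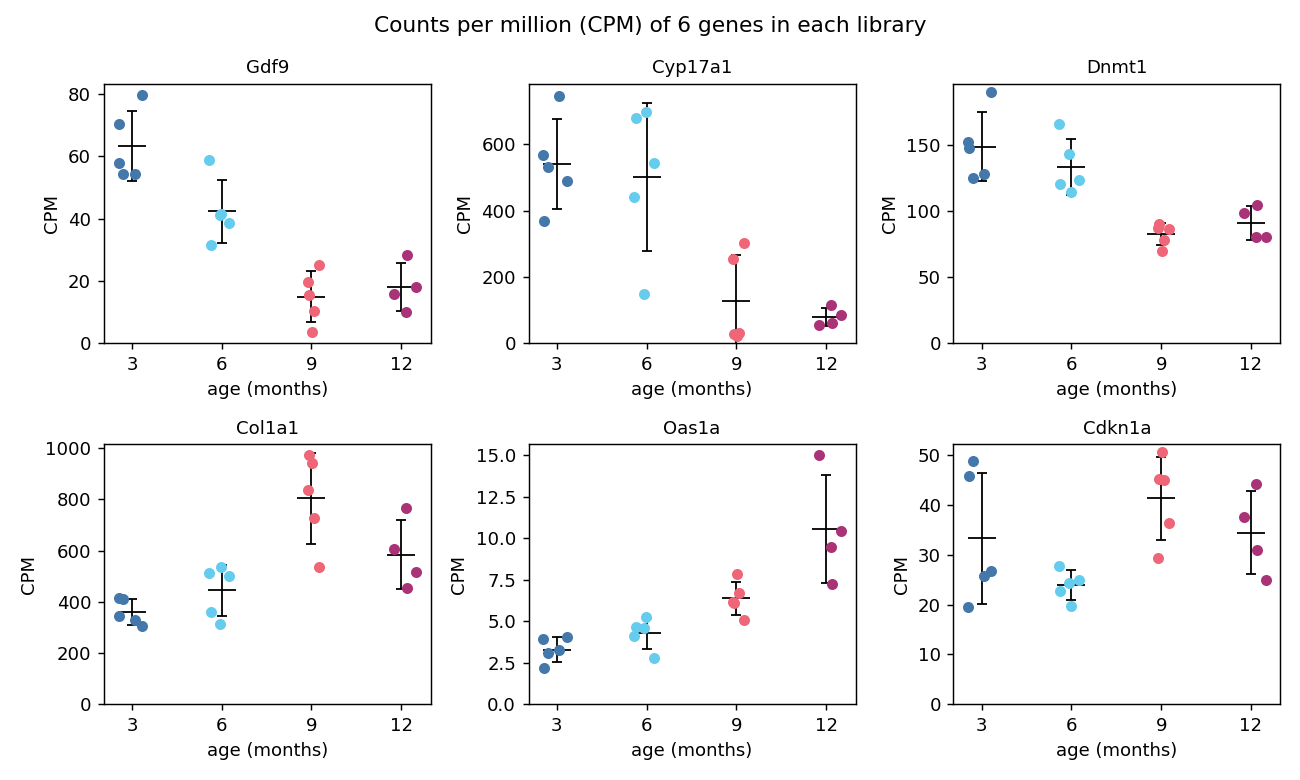
CPM (y axis, from 0) of Gdf9, Cyp17a1, Dnmt1, Col1a1, Oas1a and Cdkn1a in each library (points) by age in months (x axis), with the group mean and SD (bar and whiskers). Gdf9 is at 54.3 to 79.5 CPM in the 3 month libraries and 10.1 to 28.3 CPM in the 12 month libraries, while Cdkn1a is at 19.4 to 48.8 and 25.0 to 44.2 CPM.

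Along a straight line over the 4 ages, 30 of 30 oocyte genes fell, 30 also adjusted over the list alone (camera adjusted p = 1.45e-16; adjusted p = 0.337 with an estimated correlation). Of 24 proliferation genes 24 fell, 24 also adjusted over the list alone (camera adjusted p = 7.14e-12; adjusted p = 0.337 with an estimated correlation). Among the 15 DNA methylation genes 9 fell and 1 rose, with 9 and 1 adjusted over the list alone (camera adjusted p = 0.00417; adjusted p = 0.337 with an estimated correlation). Among the 27 interferon genes 18 rose, 20 adjusted over the list alone (camera adjusted p = 1.65e-06; adjusted p = 0.337 with an estimated correlation). Among the 10 MHC class II genes 10 rose, 10 adjusted over the list alone (camera adjusted p = 0.000177; adjusted p = 0.34 with an estimated correlation). The mean log2 CPM of this list was 5.86 and 6.21 in 9 month replicates 1 and 2, 6.57 in 12 month replicate 2 and at most 5.16 in the others. In all 2274 genes rose and 2302 fell, and 4506 genes differed between any ages (edgeR quasi-likelihood test). Gpr98, also called Adgrv1, an adhesion receptor gene, fell by 1.75 ± 0.13 over 9 months (log2, SE, n = 19; edgeR adjusted p = 1.2e-07). Arhgap29, a GTPase regulator (-0.93 ± 0.10), Pja1 (-0.55 ± 0.06), Gpr116 (-0.60 ± 0.07) and Mum1l1 (-1.27 ± 0.15) also fell with group means in age order. Rising in age order were Sema3f, an axon guidance ligand (0.86 ± 0.10), Oas1a (1.67 ± 0.21), the iron-binding lipocalin gene Lcn2 (3.22 ± 0.38), the matrix protease gene Mmp7 (2.66 ± 0.34) and the scavenger receptor gene Cd163l1 (2.79 ± 0.36). By camera 15 lists shifted up and 8 down of 36, and with an estimated correlation 0 did.

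Between 3 and 6 months 3 genes passed the edgeR quasi-likelihood test, with 1528 at an unadjusted p under 0.05. Pcdhb9, a protocadherin, rose from 14.3 ± 1.32 to 26.7 ± 2.22 CPM (SD, n = 5 and 5; edgeR adjusted p = 0.0102), and Astn1, an adhesion protein of neurons, from 2.71 ± 0.651 to 7.22 ± 0.428 CPM (edgeR adjusted p = 0.0189). Hmga2, a chromatin protein of growing cells, fell from 9.66 ± 1.56 to 4.88 ± 0.451 CPM (edgeR adjusted p = 0.0201). Oocyte genes had a median log2 change of -0.57, with 0 of 30 past the edgeR test and 0 adjusted over the list alone (camera adjusted p = 1.48e-07; adjusted p = 0.769 with an estimated correlation). Adipocyte genes had a median of -0.93, with 0 past the edgeR test and 0 adjusted over the list alone (camera adjusted p = 4.75e-06; adjusted p = 0.769 with an estimated correlation). Of 9 mast cell and granulocyte genes 0 passed over all genes and 4 rose adjusted over the list alone (camera adjusted p = 0.00673; adjusted p = 0.769 with an estimated correlation). By camera 6 lists shifted up and 6 down, and with an estimated correlation 0 did. The call on Pcdhb9 was lost without 3 month replicate 3 or 6 month replicate 3 (log2 change 0.87 and 0.88), that on Astn1 without 3 month replicate 3 or 4 or 6 month replicate 3, 4 or 5 (log2 change 1.31 to 1.42) and that on Hmga2 without 3 month replicate 3, 4 or 5 or 6 month replicate 2, 3, 4 or 5 (log2 change -1.01 to -0.92). DESeq2 called 44 genes and limma-voom 182. The edgeR count was 0 without 3 month replicate 3 and 0 without 6 month replicate 3, 5 without 12 month replicate 2, and 1 without 3 month replicate 4, 6 month replicate 4 or 6 month replicate 5.

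Between 3 and 9 months 30 of 30 oocyte genes fell (30 adjusted over the list alone), with a median of -2.09 (camera adjusted p = 3.6e-21; adjusted p = 0.168 with an estimated correlation), as did 24 of 24 proliferation genes (24 adjusted over the list alone; camera adjusted p = 9.18e-17; adjusted p = 0.168 with an estimated correlation). Of 28 collagen and matrix genes 19 rose and 1 fell (21 and 2 adjusted over the list alone; camera adjusted p = 1.66e-09; adjusted p = 0.159 with an estimated correlation), and 12 of 14 endothelial genes rose (13 adjusted over the list alone; camera adjusted p = 8.14e-09; adjusted p = 0.0865 with an estimated correlation). In all 3872 genes changed, 1754 upward and 2118 downward (edgeR quasi-likelihood test). The genes with the smallest p were Pcdhb9 (1.37 ± 0.13; log2, SE), Astn1 (1.99 ± 0.21) and Nr1d1, a circadian repressor (1.61 ± 0.17), upward. Downward they were Tnks, a telomere-associated polymerase (-0.68 ± 0.06), Rif1, a replication timing factor (-0.76 ± 0.07), and the kinase gene Prkcd (-0.88 ± 0.08). By camera 16 lists shifted up and 7 down, and with an estimated correlation 0 did. In 4 of the 9 month libraries liver transcripts were high. Alb, the serum albumin gene, chosen after its values were seen, was at 44.0, 109, 362 and 16.2 CPM in replicates 1 to 4 and 3.04 CPM in replicate 5. Of 14 genes of a liver list made after seeing the data 14 rose between 3 and 9 months. With the 4 libraries over 10 CPM of Alb left out, a setting chosen after seeing the data, 9 genes changed, and 2 between 6 and 9 months, where 2676 changed with all libraries. This keeps 1 library at 9 months, which is assumed to vary like the rest.

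The step from 6 to 9 months alone held 2676 changed genes, 1155 upward and 1521 downward (edgeR quasi-likelihood test). Oocyte genes fell in 27 of 30 cases (30 adjusted over the list alone; camera adjusted p = 9.56e-17; adjusted p = 0.213 with an estimated correlation). Proliferation genes fell in 22 of 24 cases (24 adjusted over the list alone; camera adjusted p = 1.76e-14; adjusted p = 0.213 with an estimated correlation). Of 28 collagen and matrix genes 17 rose and 1 fell (21 and 2 adjusted over the list alone; camera adjusted p = 8.9e-08; adjusted p = 0.213 with an estimated correlation). Col1a1 rose by 0.85 ± 0.18 (log2, SE), Dnmt1 fell by 0.70 ± 0.12, Tet1 fell by 0.45 ± 0.08 and Cdkn1a rose by 0.79 ± 0.23, a call lost without 6 month replicate 2 or 9 month replicate 2 or 3 (log2 change 0.72 to 0.75). Of 15 adipocyte genes 7 rose (12 adjusted over the list alone; camera adjusted p = 1.37e-05; adjusted p = 0.305 with an estimated correlation). The mean log2 CPM of that list was 7.87 in 9 month replicate 1 and 5.89 to 6.41 in the other 9 month libraries. Klf10, a TGF-beta responsive repressor (0.77 ± 0.07), and the circadian genes Dbp (2.13 ± 0.20) and Nr1d1 (1.79 ± 0.18) rose with the smallest p, and Tnks (-0.68 ± 0.06), Rif1 (-0.70 ± 0.07) and Tanc2 (-0.91 ± 0.10) fell. By camera 20 lists shifted up and 10 down, and with an estimated correlation 0 did. The count of changed genes was 1721 without 6 month replicate 5 and 1741 without 9 month replicate 3.

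**Figure D5:**
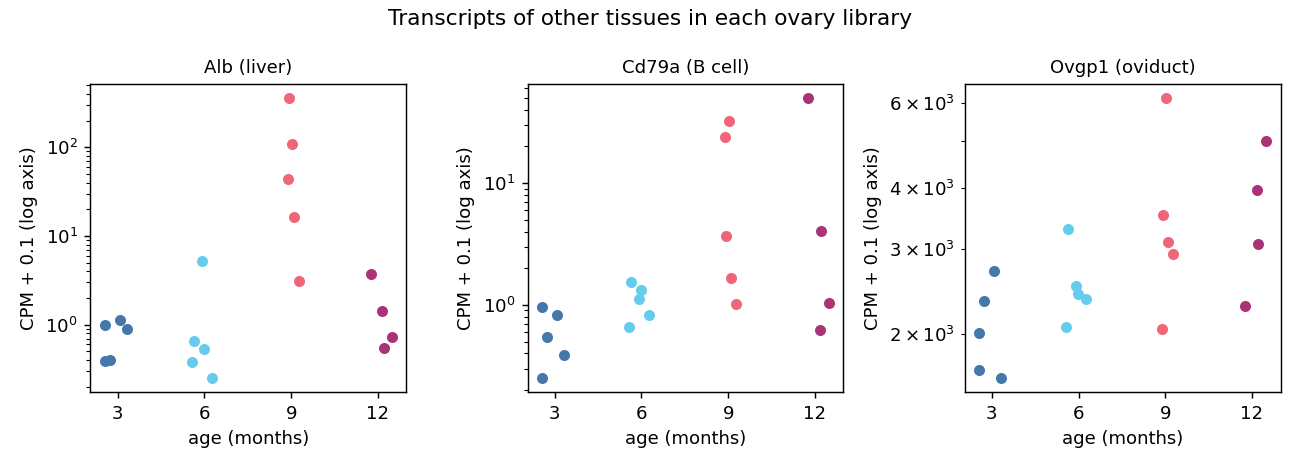
CPM plus 0.1 (y axis, log scale) of Alb, Cd79a and Ovgp1 in each library (points) by age in months (x axis). Alb is at 16.2 to 362 CPM in 4 of the 9 month libraries, Cd79a reaches 50.3 CPM in 12 month replicate 2, and Ovgp1 lies at 1624 to 6152 CPM.

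From 9 to 12 months edgeR's quasi-likelihood test called 0 genes, with 2152 at an unadjusted p under 0.05. DESeq2 called 267, 69 upward and 198 downward, limma-voom called 0 and limma-trend on the authors' log2 values 0. Of 28 collagen and matrix genes 0 passed over all genes and 9 fell when adjusted over the list alone, with a median of -0.29 (camera adjusted p = 6.83e-09; adjusted p = 0.471 with an estimated correlation). Of 15 adipocyte genes 0 passed over all genes and 7 fell when adjusted over the list alone, with a median of -1.14 (camera adjusted p = 3.71e-07; adjusted p = 0.577 with an estimated correlation). Oocyte genes had a median of 0.29, with 0 past the test and 0 adjusted over the list alone (camera adjusted p = 0.000588; adjusted p = 0.813 with an estimated correlation). Granulosa cell genes had a median of 0.42, with 0 past the test and 0 adjusted over the list alone (camera adjusted p = 0.000136; adjusted p = 0.577 with an estimated correlation). By camera 4 lists shifted up and 7 down, and with an estimated correlation 0 did. The edgeR count was 278 without 9 month replicate 5, 25 without 12 month replicate 4, 23 without 12 month replicate 2, 10 without 9 month replicate 1, 3 without 3 month replicate 1 and 2 without 3 month replicate 3.

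Genes called between 3 and 12 months were followed from 6 to 9 months, in libraries of other ages. Both comparisons come from one fit and share its filter, scaling and estimate of the spread. Of the 1693 genes that rose, 1501 (88.7%) had a higher level at 9 than at 6 months, and of the 1782 that fell, 1678 (94.2%) had a lower level. Of these, 414 and 937 also passed the edgeR test there in the same direction. Genes are not independent of one another, so no p-value was computed from their number. Both comparisons set later numbered libraries against earlier ones. A difference in handling or in time of day between them would also give the same direction, so these shares are no separate check of age.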

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

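The tests of the step between 6 and 9 months, of lymph node and liver transcripts and of the clock genes were chosen after the result was seen, and the counts over other splits of the libraries were not.

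Between 6 and 9 months 2676 genes changed, and the tables argue against 3 technical sources as the whole of it. With a correction for gene length and GC content 2546 genes were called, and 2051 of the 2676 (76.6%) were among them. With the oviduct list as a covariate 2924 were called, with 2363 (88.3%) of the 2676 among them. With the libraries that hold lymph node transcripts left out 2118 were called, with 1710 (63.9%) among them. With the 4 libraries of high liver transcripts left out 2 genes were called, and the oocyte median was -0.91 against -1.52 with all libraries. That fit keeps 1 library at 9 months, so whatever set those libraries apart stays open. Age itself is also open and was not tested apart from these.

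Lymphocyte and liver transcripts were high in some libraries, which may reflect tissue from outside the ovary. Of 7 lymph node genes outside the lymphocyte lists, 7 had their 3 highest libraries in the same 3, in line with lymph node tissue as the source of the highest libraries. Those 3 libraries were not the whole source of the rise: with them left out, 5 of 10 B and plasma cell genes still rose between 3 and 12 months. Leaving out libraries by a cut on Cr2 cannot exclude smaller amounts of lymph node tissue in the libraries kept. Of the liver genes other than Alb, 13 of 13 had the same 4 highest libraries as Alb, consistent with liver RNA from outside the ovary. Alb was at 0.45 to 3.6 CPM at 12 months and 1 of 14 liver genes rose between 3 and 12 months, so the high level of 9 months was not seen there, but none of the 14 passed the edgeR test between 9 and 12 months, and age stays open for both.

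Clock genes differed between 6 and 9 months and between 3 and 12 months, and a candidate explanation is another time of day at collection, which the labels do not give. Between 6 and 9 months genes driven by the activator Bmal1 rose in 6 of 8 cases, Dbp by 2.13 ± 0.20 and Nr1d1 by 1.79 ± 0.18 (log2, SE), and genes of the opposite phase fell in 3 of 6 cases, Cry1 by 0.93 ± 0.14, chosen after its values were seen. Of the opposite phase Arntl (-0.08 ± 0.12), Nfil3 (-0.11 ± 0.16) and Npas2 (0.37 ± 0.26) did not pass the test over this step. Nor did Per2 (-0.19 ± 0.14) and Per3 (0.11 ± 0.10) of the genes driven by Bmal1. The list medians were 0.51 and -0.17, a difference of 0.68. Between 3 and 12 months 5 of 8 rose and 5 of 6 fell, with medians of 0.31 and -0.58, a difference of 0.89. Gene length and GC content do not account for the first of these as a whole: 8 of 9 called clock genes stayed called with that correction, and age stays open for both, untested.

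Single libraries lay far from the others of their age in 19 of 308 groups of values (6.2%), where chance flags about 1 in 20 groups. 12 month replicate 2 stood apart in the share of counts from the ribosomal RNA gene Rn45s (0.785% against 0.229 to 0.313%). Its mean log2 CPM stood apart for granulosa cell genes (6.5 against 7.09 to 7.14), matrix protease genes (5.5 against 5.29 to 5.32) and MHC class II genes (6.57 against 4.95 to 5.16), and its Glycam1 level was 33.97 CPM against 0.15 to 0.3 CPM. 12 month replicate 4 was apart in theca and interstitial genes (6.78 against 6.28 to 6.36) and 9 month replicate 1 in adipocyte genes (7.87 against 5.89 to 6.41). Among 6 month libraries, replicate 5 had a PC1 score of -30.84 against -16.49 to -11.28, an Obox5 level of 11.65 CPM against 5.45 to 5.99 CPM and a Sema3f level of 24.2 CPM against 26.98 to 28.14 CPM. Replicate 2 of that age was apart in antioxidant genes (7.03 against 6.92 to 6.94) and complex I genes (6.01 against 5.91 to 5.93). Replicate 1 of that age was apart in senescence inhibitor genes (5.56 against 5.16 to 5.23) and Cdkn2a (2.92 CPM against 0.8 to 1.15 CPM). 3 month replicate 3 was apart in primordial follicle oocyte genes (3.23 against 2.7 to 2.84), B and plasma cell genes (1.36 against 0.7 to 0.86), Obox5 (15.71 CPM against 9.49 to 10.93 CPM) and Glycam1 (0.14 CPM against 0.0), and 3 month replicate 5 in Lcn2 (10.79 CPM against 13.2 to 13.98 CPM).

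Chance was weighed by regrouping the libraries, with 100 splits for each result, the real one included. For the genes changed between 3 and 12 months 1 split gave as many as the real 3475, and the highest other gave 1442. The same held for the trend (1, real 4576, highest other 3171), any age (1, 4506, 1584), 9 against 3 months (1, 3872, 1401) and 9 against 6 months (1, 2676, 164). This excludes chance for these counts only to 1 in 100, and only if each library came from a separate mouse, which the labels do not say. Between 3 and 6 months 1 split gave as many as the real 3 (highest other 0), but the real count was itself 0 without 3 month replicate 3 or 6 month replicate 3 and 1 without 3 month replicate 4 or 6 month replicate 4 or 5, so the count past the threshold depends on single libraries. The levels of the 3 genes did not overlap between these ages. They were called from these same libraries, so the lack of overlap is no separate support. Pcdhb9 was at 12.8 to 15.6 CPM at 3 months and 23.1 to 28.6 CPM at 6 months. Astn1 was at 1.94 to 3.51 and 6.57 to 7.69 CPM, and Hmga2 at 8.25 to 11.4 and 4.47 to 5.57 CPM. For the share of genes with the same direction 1 split gave as much as the real 91.5% (highest other 90.2%). In every other split 6 month replicate 1 was labelled 9 months, and the mirror image of a split was not run. A mirror image turns a low share into a high one, so this count cannot exclude chance. The real share lay under that value by DESeq2 (90.1%), without 9 month replicate 2 (87.2%), 12 month replicate 2 (87.3%) or 12 month replicate 4 (89.9%), and without the lymph node (80.8%) or the liver libraries (76.1%). The other splits were not run under those settings, and chance is not excluded for the share under any of them or with all libraries. For the lists chance cannot be excluded: 7 splits gave as many lists as the real 21 between 3 and 12 months (highest other 23) and 5 as many as the real 23 along the trend (highest other 27). Between 9 and 12 months the real count was 0 by edgeR, so 100 of 100 splits give as many by construction and nothing about chance follows; 2152 genes had an unadjusted p under 0.05 and DESeq2 called 267. There 11 other splits called more than 100 genes and the highest 573, and what set those splits apart was not tested.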

How the results depend on the processing

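Settings that leave out libraries by their lymph node or liver transcripts, the length and GC correction and the oviduct covariate were chosen after seeing the data. Of 4069 values of named genes under other settings 3841 kept direction and side of the threshold, 178 lost the call, 50 gained one and 0 reversed. With 1 library left out the numbers were 5890 of 6194, 268, 35 and 1, the last being Bhmt between 3 and 12 months without 12 month replicate 4 (-0.456, against up to 4.16 in the other fits of this kind), the 12 month library with its high level. Between 3 and 6 months (3 genes) the count was 44 by DESeq2, 182 by limma-voom, 6 with 2 surrogate variables, 34 with only those ages fitted and 8 without the lymph node libraries. Between 9 and 12 months (0 genes) it was 267 by DESeq2, 38 with 2 surrogate variables and 38 with the corpus luteum covariate, and the cause was not tested. Without the liver libraries, with 1 library left at 9 months, it was 2614 for any age, 9 for 9 against 3 months and 2 for 9 against 6 months. With an adjusted p under 0.01 the counts were 1354 (12 against 3 months), 2349 (trend), 2060 (any age), 0 (6 against 3), 1872 (9 against 3) and 994 (9 against 6). With at least a doubling or halving they were 762, 1050 (trend), 1, 895 and 506; that threshold has no value for any age. The share with the same direction was 90.1% by DESeq2, 95.9% under 0.01, 80.8% without the lymph node and 76.1% without the liver libraries. With an estimated correlation 0 and 0 lists were called, as that setting lets members move together.

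Leaving out 1 library in turn, counts ran from 2124 to 3806 (12 against 3 months), 3798 to 4853 (trend), 3638 to 5103 (any age), 0 to 5 (6 against 3), 2784 to 4484 (9 against 3), 1721 to 3212 (9 against 6) and 0 to 278 (12 against 9). The lowest count for 12 against 3 months was without 12 month replicate 3, and the lowest for 9 against 6 months without 6 month replicate 5. For 12 against 9 months the highest was without 9 month replicate 5. The share with the same direction ran from 87.2% to 94.9%, and lists from 18 to 23 (12 against 3 months) and 21 to 24 (trend). The median change of all genes lay between -0.009 and 0.033 (log2) in the comparisons under TMM and 3 other scalings. No paired analysis was possible because the labels share no replicate numbers between ages.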

Other observations

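Further lists fixed in advance held genes that changed between 6 and 9 months (edgeR's quasi-likelihood test). Of 20 granulosa cell genes 6 fell between 6 and 9 months (11 adjusted over the list alone; camera adjusted p = 1.03e-05; adjusted p = 0.245 with an estimated correlation), with Amh (-1.50 ± 0.30; log2, SE), Esr2 (-0.98 ± 0.20) and Slc18a2 (-1.35 ± 0.27) among them. Of 36 nuclear genes of mitochondrial complex I 6 rose over the same step, 6 also adjusted over the list alone (camera adjusted p = 7.18e-06; adjusted p = 0.304 with an estimated correlation), Ndufa1 by 0.26 ± 0.07, a call lost without 6 month replicate 5 or 9 month replicate 3 (log2 change 0.24 to 0.25). That list had a median of -0.11 between 3 and 6 months (0 rose and 0 fell by edgeR's test, 0 and 0 adjusted over the list alone; camera adjusted p = 1.48e-07; adjusted p = 0.769 with an estimated correlation) and of 0.01 between 3 and 9 months (camera adjusted p = 0.339). Of 30 senescence associated secretory genes 7 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.00735; adjusted p = 0.285 with an estimated correlation). Pck1, the gluconeogenic enzyme of fat and liver, rose by 3.79 ± 0.63, and was at 199 CPM in 9 month replicate 1 and at 33.4 to 72.1 CPM in the other 9 month libraries.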
